A study of Mus musculus with 15 samples.

How the data were processed

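RNA sequencing was done on 15 libraries from 5 populations of 4T1 cells, a mouse mammary carcinoma line, with 3 biological replicates of each population. The populations were the parental line and the clonal populations E1, E2, A and M, each grown from 1 parental cell that carried a plasmid for a nuclear near-infrared fluorescent protein. Per the labels, the clones were kept in G418, which was taken away before RNA was collected, and RNA was taken after 72 h of culture at about 80% confluency.

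The raw counts per gene were made by the authors with HISAT2 and featureCounts, and the builds named in their notes are GRCm38 and mm10. The tool versions are not stated there, nor is the strand setting of the counting, so reads of genes that overlap on opposite strands cannot be told apart. Values of genes with near-identical copies, such as ribosomal protein, histone, H2 and small RNA genes, are uncertain for the same reason of shared reads. The deposited normalized counts are a signal: each value was the count of the same gene divided by 1 constant per library, between 0.692 and 1.47, and they served only to check the counts. The authors' DESeq2 table gives log2 fold changes with their standard errors, and the deposited p-values and adjusted p-values of 1 comparison whose populations the file does not name. It was only compared with the fits made here. The deposited log-scale transformations of the same libraries were not used here.

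Gene identifiers were joined to symbols and GRCm38 coordinates with a RefSeq gene table, and with the Entrez links of GENCODE where that table lacked them. Of 27179 identifiers, 25275 were named by the first source, 18 by the second, and 1886 stayed unnamed. Counts were analysed with R 4.3.3, edgeR 4.0.16 and limma 3.58.1. The filter filterByExpr (minimum count 10, minimum total count 15, the 5 populations as groups) kept 12712 genes, TMM gave factors between 0.847 and 1.11, and a robust quasi-likelihood fit with the population as its only term gave F tests of the 10 pairs of populations and of any difference among the 5. The common dispersion was 0.0651, a biological coefficient of variation of 0.255. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, adjusted within each comparison. Fold changes used a prior count of 2. A population was said to be set apart by a gene called against each of the other 4 populations, in 1 direction, with an absolute log2 fold change of at least 1.

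Values are CPM, counts scaled by edgeR to the TMM-adjusted total of their library, given as the mean and standard deviation (SD) over 3 libraries. The standard error (SE) of a log2 fold change was computed from the SD of log2 CPM in the 2 populations. A population whose libraries all had 0 counts was given a floor of 3 counts over the population, 0.0318 to 0.0378 CPM, and fold changes against it are lower bounds. SD, floors and bounds of this kind cover replicate spread or counting error only, and reads without molecular identifiers are not independent molecules.

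Before the data were examined, 35 gene lists, the comparisons, the tests, the alternatives and the rule for naming genes were fixed. The lists covered epithelial, mesenchymal, luminal and basal mammary genes, proliferation, p53, YAP, Wnt, Notch, and TGFb and BMP signalling, NRF2 targets, the ATF4 and endoplasmic reticulum stress response, heat shock, hypoxia, glycolysis, oxidative phosphorylation, mitochondrially encoded genes, fatty acid and cholesterol synthesis, interferon response, class I antigen presentation, cytokines, extracellular matrix, proteases, integrins, actomyosin, stem cell genes, growth factors and receptors, drug efflux, immediate early genes, ribosomal proteins, replication-dependent histones, and markers of leukocytes, fibroblasts and endothelial cells. Lists with at least 5 tested genes, 32 of the 35, were tested with camera at a preset correlation of 0.01, with 1 adjustment over the 4 comparisons with the parental population and 1 over the 6 comparisons between clones. Camera with an estimated correlation and fry were the alternatives. Some lists were set down beforehand as signs of RNA quality, library type and handling. They were mitochondrially encoded genes, ribosomal proteins, replication-dependent histones, immediate early genes and heat shock.

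The rule for naming genes took genes with a symbol that is not that of a predicted model, at least 5 CPM in the higher population, a call, and 3 replicates of 1 population all above the 3 of the other. It took the 10 largest log2 fold changes in each direction against the parental population, the 4 largest in each direction between clones, up to 6 higher and 4 lower genes per population set apart, and up to 4 members per called list. Genes named beside the rule are marked as chosen after their values were seen. A result for 1 gene that the rule took is not reported here.

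Gene counts and named genes were recomputed with RLE size factors, with no filter, with a filter of more than 1 CPM in at least 3 libraries, with DESeq2 1.42.0, with the replicate number as a block, with only the 6 libraries of a comparison where it has 2 populations, and without each library in turn. Gene lists were recomputed with RLE size factors, with the block and without each library in turn. Added after the data were seen were a fit without the 6 genes with the most counts, a covariate for the share of the top gene, a fit without the 2 libraries with the highest such share, and a DESeq2 likelihood ratio test for any difference among the populations. The method was tested on simulated data with known changes in A against the parental population, where 59% of 2-fold and 85% of 4-fold changes were called and 5 of 151 calls (3.3%) were unchanged genes. Chromosomal regions were searched with medians of 50 neighbouring genes at steps of 25, against 1000 shuffles of the gene order. Figures were drawn with Python and matplotlib.

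Library totals ran from 20143111 to 36831801 counts. The 6 genes with the most counts, among them the mitochondrial rRNA genes mt-Rnr1 and mt-Rnr2, Lars2 and 3 identifiers without a symbol in the reference, took 61.4% to 72.1% of them, which left 6164768 to 14206491 counts for all other genes.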

Results

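Gene expression was measured by RNA sequencing in 5 populations of 4T1 cells, a mouse mammary carcinoma line: the parental population and the clonal populations E1, E2, A and M, each derived from a single parental cell. There were 3 biological replicates of each population and 15 libraries in all. The libraries held 20143111 to 36831801 counts, and 13173 to 14294 genes had at least 1 count in a library. A single identifier without a symbol, 100861531, took 36.8% to 49.3% of the counts of a library, Lars2 took 8.41% to 13.3%, and mt-Rnr1 and mt-Rnr2 together took 6.71% to 13.2%. The highest shares of the first were in parental replicate 1 (49.3%) and E2 replicate 1 (49.1%). The product of 100861531 was not identified, and whether the counts of Lars2 are transcripts of that gene was not tested. These shares are therefore not read as expression levels. The 6 genes with the most counts took 61.4% to 72.1% of a library. They are part of the total to which every CPM value is scaled. Outside these 6 genes, 6164768 to 14206491 counts remained per library. These limit the counting precision of all other values, to which the spread between replicates adds.

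The study compares clonal populations derived from 1 parental line, so the first question was how far the populations differ. Of 12712 genes tested, 5200 (40.9%) differed among the 5 populations. The first principal component (24.8% of the variance) separated A from the other 4 populations, and the second (17.2%) separated the parental libraries from the clones. The mean correlation of log2 CPM between libraries of 1 population was 0.955 to 0.964. It was 0.957 between E1 and E2, 0.930 between A and M, and 0.911 between E1 and A, across genes, which are not independent replicates.

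**Figure D1:**
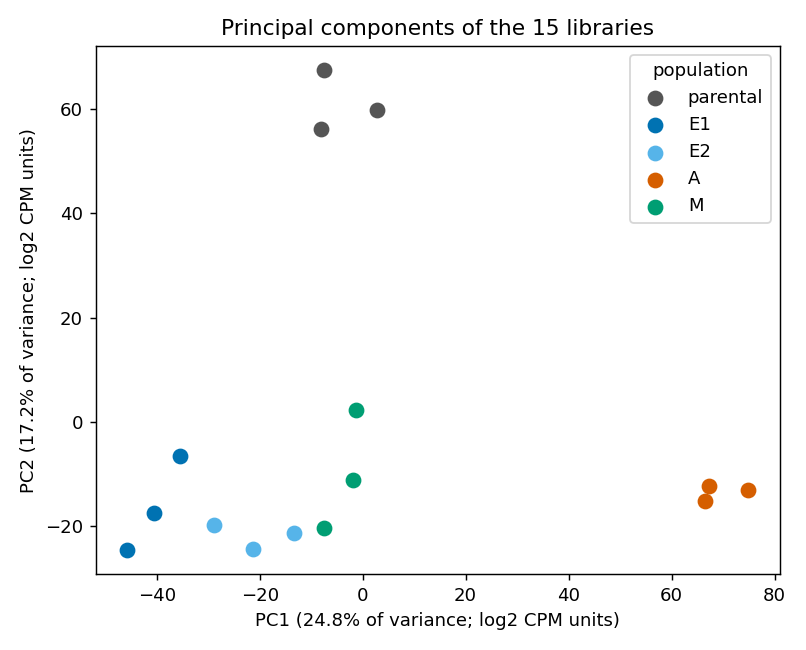
Scores of the 15 libraries on the first and second principal components of log2 CPM, 1 point per library, coloured by population. The components hold 24.8% and 17.2% of the variance, and the 3 A libraries and the 3 parental libraries each lie apart from the rest.

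Against the parental population, A had the most genes called, 3814 (1924 higher and 1890 lower), of which 1697 changed at least 2-fold. E2 had 2281 (1162 higher and 1119 lower), E1 had 1922 (988 higher and 934 lower) and M had 1798 (1000 higher and 798 lower). Replicates of the 2 populations did not overlap for 33.4% of tested genes in E1, 32.6% in E2, 44.6% in A and 29.3% in M, where chance gives 10% for 3 against 3. Without E1 replicate 2 or 3 the E1 count was 1084 or 1173, and without M replicate 3 the M count was 1145.

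**Figure D2:**
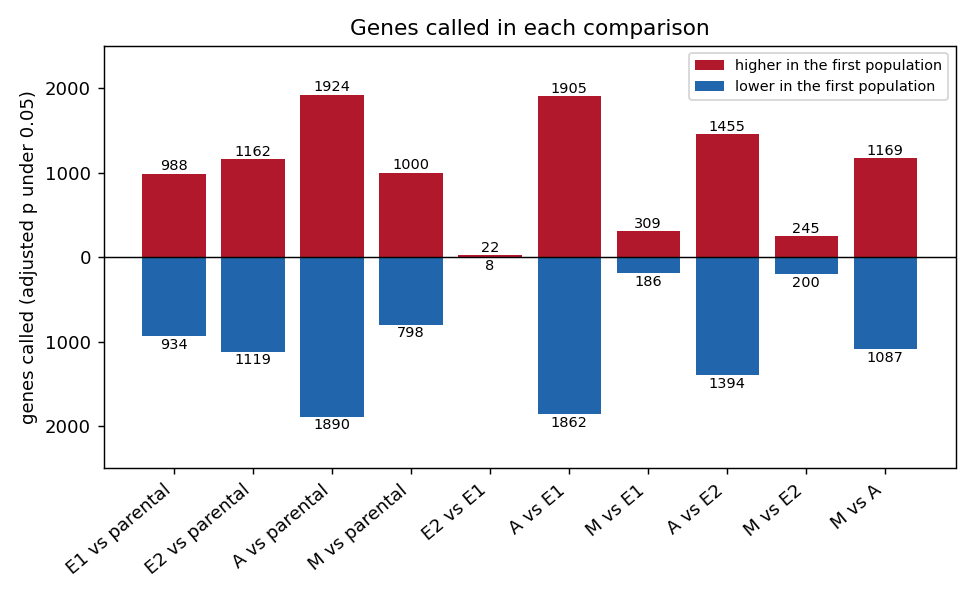
Number of genes called in each of the 10 comparisons (edgeR, adjusted p under 0.05), with genes higher in the first-named population above 0 and genes lower in it below 0. A against the parental population had 3814 calls and E2 against E1 had 30.

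What the clones share was asked first. In all 4 clones, 532 genes differed in 1 direction from the parental level, 311 higher and 221 lower, and without parental replicate 3 the count was 354. For expression, rose and fell mean higher and lower than in the parental population, since the founder cells were not measured. Independent calls at these rates would give 1.84 shared genes. Simulated libraries without differences shared 0, but they had a mean of only 0.1 to 0.2 calls per comparison. Hardly any gene could be shared there, so that 0 does not measure what the parental libraries add. The 4 comparisons use the same 3 parental libraries, which are too few to be divided, so part of the overlap in calls can come from them. The covariance of log2 fold changes between clones was 0.255 to 0.484 over the 6 pairs, where simulated libraries without differences gave 0.089 to 0.09. The excess of 0.164 to 0.395 estimates what the pairs share beyond independent noise in the parental libraries. A shift common to all 3 parental libraries would also fall into this excess and cannot be told apart here. Of all genes, 154 set the parental population apart at 2-fold or more against each clone, 40 higher in the parental cells and 114 lower. Transfection, single-cell isolation and G418 were common to all 4 clones. Their effects cannot be told apart from what the clones share.

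The parental cells expressed Mal2, a transcytosis protein of epithelial cells (identifier 105853, chromosome 15, 54571366 to 54602846, GRCm38), at 21.6 CPM ± 4.50 (SD, n = 3), and the clones at 0.0205 to 0.318 CPM. The log2 fold change was -7.54 in E1, -6.59 in E2, -7.91 in A and -5.81 in M. Gpm6b, a membrane glycoprotein, was at 8.26 CPM ± 2.37 in the parental cells and at 0.0327 CPM ± 0.0566 in M, with log2 fold changes from -6.27 in M to -2.88 in A. Aldh1l2, an enzyme of mitochondrial folate metabolism, fell from 24.9 CPM ± 2.87 to between 2.46 and 4.18 CPM. Vldlr, a lipoprotein receptor, fell from 44.1 CPM ± 9.32 to between 3.16 and 12.2 CPM. The kinesin gene Kif21b and Plekhh2 were also higher in the parental cells, at 8.41 CPM ± 0.487 and 6.68 CPM ± 1.05, but the call of Kif21b in E1 was lost with DESeq2 and without E1 replicate 1 or 2 (adjusted p up to 0.0846). That of Plekhh2 was lost in E2 without any 1 of 5 libraries (up to 0.119) and in E1 without parental replicate 2 or E1 replicate 2 or 3 (up to 0.0857). Without both libraries with the highest share of the top gene, the calls of both genes were lost in E1 and E2 (0.0515 to 0.0922).

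In the other direction, Thbs1, a secreted matrix glycoprotein (identifier 21825, chromosome 2, 118111876 to 118127133), stood at 83.2 CPM ± 11.7 in the parental cells and at 530 CPM ± 54.2 in E1, 670 CPM ± 57.5 in E2, 526 CPM ± 151 in A and 408 CPM ± 117 in M. Gatm, the first enzyme of creatine synthesis (identifier 67092, chromosome 2, 122594473 to 122611277), rose from 1.04 CPM ± 0.198 to 18.5 CPM ± 0.556 in E1, 14.3 CPM ± 0.592 in E2, 7.75 CPM ± 1.05 in A and 11.5 CPM ± 1.41 in M. The serine protease gene Prss22 rose from 2.06 CPM ± 1.21 to between 14.1 and 39.9 CPM, and the receptor gene Havcr2 from 0.730 CPM ± 0.642 to between 5.53 and 11.6 CPM.

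Gene lists fixed before the data were examined were tested next. With camera at its preset correlation, 43 of 128 tests of a clone against the parental population were called, 26 upward and 17 downward, and 28 without parental replicate 2. With an estimated correlation 1 of these held, the ATF4 and endoplasmic reticulum stress list in A (adjusted p = 0.0149). Fry called 53, of which 36 were also called by camera. Random regroupings of the 15 libraries gave up to 36 list calls (median 24), though such groups can still carry differences between populations. Each list is therefore given with the calls of its members unless stated. A list is said to rise or fall by the direction camera gives it against all other genes, whether or not its members were called.

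**Figure D3:**
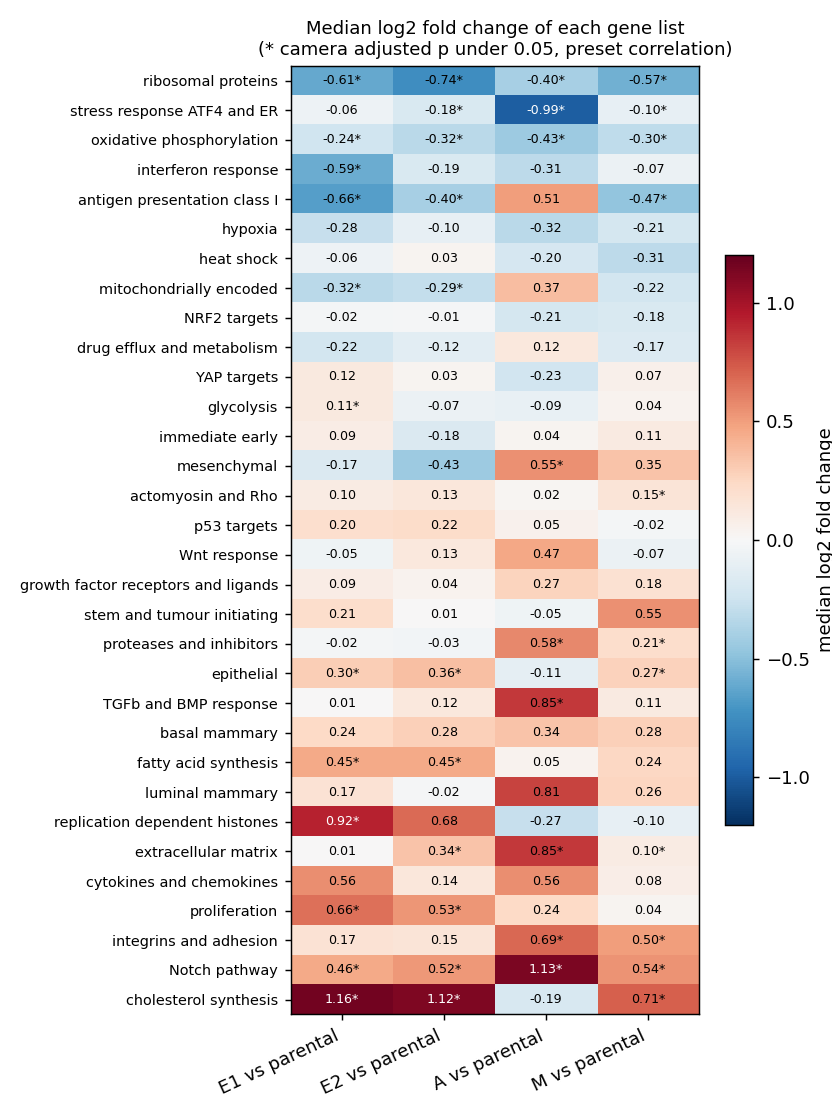
Median log2 fold change of the tested members of each of 32 gene lists (vertical axis) in each clone against the parental population (horizontal axis), red for higher and blue for lower, with an asterisk at a camera adjusted p under 0.05. Ribosomal proteins were lower in all 4 clones, from -0.40 in A to -0.74 in E2, and cholesterol synthesis was higher in E1 (1.16) and E2 (1.12).

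Ribosomal protein genes fell in all 4 clones. This list was set down beforehand as a sign of RNA quality, library type and handling. So were the mitochondrially encoded, histone and immediate early lists reported below, and none of them can be read as biology alone. Of 39 members, 23 were called lower in E1 (28 when adjusted over the list alone), 26 in E2 (33), 14 in A (14) and 18 in M (27), and 0 were called higher. The list's median log2 fold change was -0.61, -0.74, -0.40 and -0.57, with adjusted p of 7.5e-12, 2.47e-17, 0.000133 and 1.17e-11, and adjusted p = 0.238 to 0.487 with an estimated correlation. Rpl4 stood at 493 CPM in the parental cells and fell by 1.09 ± 0.110 (SE, log2 scale, n = 3) in E1, 1.19 ± 0.0920 in E2 and 0.93 ± 0.0800 in M. Rps24 fell by 1.56 ± 0.104 in E2, and Rps2 by 1.11 ± 0.145 in A. Oxidative phosphorylation genes were lower in all 4, with 5 of 42 members called lower in E1 (5 when adjusted over the list alone), 8 in E2 (8), 14 in A (15) and 8 in M (8), medians of -0.24, -0.32, -0.43 and -0.30, and adjusted p = 0.277 to 0.546 with an estimated correlation. The E1 call (adjusted p = 0.0409) was lost without parental replicate 2 or E1 replicate 1 (up to 0.112) and without both libraries with the highest share of the top gene. Ndufb9, a subunit of the first respiratory complex, fell by 2.69 ± 0.186 in A and by 2.85 ± 0.291 in M. Notch pathway genes rose in all 4, with 5 of 14 called higher in E1, 4 in E2, 7 in A and 4 in M, the same numbers when adjusted over the list alone except 8 in A and 5 in M, and 1 and 2 called lower in E1 and A. Their medians were 0.46, 0.52, 1.13 and 0.54, and adjusted p = 0.231 to 0.238 with an estimated correlation. The E1 call was lost without parental replicate 1 or 2 (adjusted p up to 0.0682) and without both libraries with the highest share of the top gene, and the M call without parental replicate 2 (0.0516). The ligand Dll1 rose by 1.61 ± 0.404, 2.32 ± 0.411, 1.97 ± 0.369 and 2.28 ± 0.355, and the target Hes1 by 1.23 ± 0.251, 1.29 ± 0.215, 2.11 ± 0.247 and 1.39 ± 0.256.

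E1 against the parental population asks how 1 clone differs from its source. Igsf11, an adhesion protein of the immunoglobulin family, rose from 0.348 CPM ± 0.239 to 15.6 CPM ± 3.04 (log2 fold change 5.17, SE 0.613, adjusted p = 1.16e-08). The noncoding RNA gene Lncenc1 rose from 2.60 CPM ± 0.739 to 86.1 CPM ± 8.40 (5.00, SE 0.242). Cldn9, a tight junction protein, rose from 0.171 to 5.12 CPM ± 0.296, and Bcl2l15, Mettl7b, Fgfbp1, Serpinb5 and Rab32 rose by 2.93 to 4.17 on the log2 scale. Among the lower genes, Fam111a fell from 5.89 CPM ± 0.777 to 0.0620 CPM ± 0.107, Dzip1 from 6.89 to 0.0885 CPM, and Hexa, a subunit of lysosomal hexosaminidase, from 5.13 to 0.0807 CPM. Rbpms, Serpine2, Hhip, an inhibitor of hedgehog signalling, and Tgfbr3, a coreceptor for TGF-beta, fell by 4.96, 4.95, 4.07 and 3.78 on the log2 scale.

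In E1, cholesterol synthesis genes rose together: 15 of 23 were called higher and 0 lower (18 higher when adjusted over the list alone), with a median log2 fold change of 1.16 and an adjusted p of 2.44e-11 (adjusted p = 0.321 with an estimated correlation). Insig1, a regulator of sterol sensing (identifier 231070, chromosome 5, 28071412 to 28078662), rose from 8.96 to 49.5 CPM, and Cyp51 from 12.9 to 49.0 CPM. Fatty acid synthesis genes rose (5 of 18 called higher, 8 when adjusted over the list alone, median 0.45), as did epithelial genes (10 of 32 higher and 0 lower, 10 and 1 when adjusted over the list alone, median 0.30), with Cldn3, Esrp1, Krt7 and Epcam at 1.92 ± 0.271, 1.41 ± 0.0590, 1.37 ± 0.192 and 1.35 ± 0.060. With an estimated correlation the adjusted p of these was 0.401 and 0.238. Proliferation genes rose, with 5 of 34 called higher and a median of 0.66 (5 when adjusted over the list alone), and Bub1 and Rrm2 at 1.41 and 1.28, and adjusted p = 0.489 with an estimated correlation. The replication-dependent histone list was called upward with 2 of 18 members called higher (2 when adjusted over the list alone; adjusted p = 0.638 with an estimated correlation), and the call was lost with fry and without parental replicate 2 (0.0516). Glycolysis genes had 6 of 20 called higher and 1 lower, the same when adjusted over the list alone, with Pgk1 at 1.02 ± 0.213 (adjusted p = 0.503 with an estimated correlation). That call was lost with fry (0.0543) and without parental replicate 2 or 3 (up to 0.0805).

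Also in E1, class I antigen presentation genes fell, with 13 of 22 called lower and 2 higher (the same when adjusted over the list alone) and a median of -0.66 (adjusted p = 0.238 with an estimated correlation). Mitochondrially encoded genes fell, 2 of 15 called lower (2 when adjusted over the list alone), median -0.32, with mt-Co1 at -0.94 ± 0.128 and adjusted p = 0.554 with an estimated correlation. Their call was lost without parental replicate 2 (0.0786). The interferon response list had 5 of 27 called lower and 1 higher, the same when adjusted over the list alone (adjusted p = 0.0407, 0.238 with an estimated correlation). Its call was lost in 13 of the 15 fits that leave out a library (up to 0.182), without the 6 genes with the most counts, with the top gene's share as a covariate and without both libraries with the highest share of the top gene.

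E2 against the parental population asks the same of a second clone, and 1327 genes were called in the same direction in E1 and E2 (722 higher and 605 lower, where independent lists would share 90.3 and 82.2), with 1 called in opposite directions. Igsf11 rose to 10.7 CPM ± 1.02 (log2 fold change 4.63, SE 0.598), Lncenc1 to 61.4 CPM ± 9.79 (4.52, SE 0.262) and Serpinb5, a serpin of epithelial cells, from 0.519 to 8.72 CPM ± 1.02 (3.89, SE 0.321, adjusted p = 3.16e-06). Postn, a matrix protein (identifier 50706, chromosome 3, 54359267 to 54391041), rose from 0.768 CPM ± 0.589 to 11.3 CPM ± 2.41. Car9, a carbonic anhydrase, rose from 1.37 to 10.3 CPM, and Fgfbp1 and Mgst3 rose by 3.57 and 2.77 on the log2 scale. Hexa, Serpine2, Myo5c, Dzip1, Rbpms, Fam111a and Hhip fell by 3.00 to 4.65 on the log2 scale.

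In E2, cholesterol synthesis genes rose again, 17 of 23 called higher (18 when adjusted over the list alone) with a median of 1.12 and Insig1 at 61.2 CPM (adjusted p = 0.304 with an estimated correlation). Fatty acid synthesis genes rose with 8 of 18 called higher (8 when adjusted over the list alone; 0.29 with an estimated correlation). Epithelial genes had 10 of 32 called higher and 1 lower (10 and 2 when adjusted over the list alone; adjusted p = 0.361 with an estimated correlation), with Esrp1 at 1.71 ± 0.0940. Proliferation genes had 9 of 34 higher (9 when adjusted over the list alone), with Bub1 at 1.33 ± 0.322 (adjusted p = 0.52 with an estimated correlation). The extracellular matrix list had 10 of 24 higher and 5 lower (11 and 6 when adjusted over the list alone), with Col12a1 at 2.42 ± 0.158 and Has2, a hyaluronan synthase, at 1.92 ± 0.309 (adjusted p = 0.635 with an estimated correlation), and its call was lost with fry (0.0967) and without parental replicate 2 or E2 replicate 3 (up to 0.126). The ATF4 and endoplasmic reticulum stress list fell, with 7 of 28 called lower and 1 higher (10 and 2 when adjusted over the list alone), and Hspa5, the main chaperone of that compartment, at -1.47 ± 0.137 (adjusted p = 0.238 with an estimated correlation). Class I antigen presentation had 6 of 22 lower and 2 higher (7 and 2 when adjusted over the list alone; adjusted p = 0.426 with an estimated correlation), a call lost without parental replicate 1 or 2 or E2 replicate 1 or 3 (up to 0.0646) and without both libraries with the highest share of the top gene. Mitochondrially encoded genes had 2 of 15 lower (2 when adjusted over the list alone; adjusted p = 0.638 with an estimated correlation), a call lost with fry (0.0967) and without parental replicate 2 or E2 replicate 1 (up to 0.207).

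A against the parental population gave the most calls of the 4. Tfpi, an inhibitor of tissue factor (identifier 21788, chromosome 2, 84432855 to 84476775), had 0 counts in the parental libraries and 6.12 CPM ± 2.65 in A, at least 162-fold higher. Dmp1, a phosphoprotein of mineralized matrix (identifier 13406, chromosome 5, 104197575 to 104214102), rose from 0.153 to 14.2 CPM ± 4.39 (log2 fold change 5.96, SE 0.489, adjusted p = 4.08e-09). Spp1, osteopontin (identifier 20750, chromosome 5, 104435111 to 104441053), rose from 116 CPM ± 31.2 to 1373 CPM ± 125. Mmp3, a matrix metalloprotease, rose from 8.51 CPM ± 3.08 to 139 CPM ± 30.3, and Sema7a, a semaphorin, from 2.03 to 41.2 CPM. S100a16, Cldn9, Fbln1, Edil3 and Efr3b rose by 3.98 to 4.81 on the log2 scale. Atf3, a stress-induced transcription factor, fell from 20.1 CPM ± 2.24 to 2.03 CPM ± 0.495, Hmox1, heme oxygenase, from 9.22 to 0.849 CPM, and Ank2, Adh7 and Ctsc by 2.97 to 3.26 on the log2 scale.

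The ATF4 and endoplasmic reticulum stress list fell most clearly in A: 19 of 28 members were called lower and 0 higher (20 and 2 when adjusted over the list alone), with a median log2 fold change of -0.99 and an adjusted p of 5.65e-13 (adjusted p = 0.0149 with an estimated correlation). Hspa5 fell from 985 to 220 CPM. Extracellular matrix genes rose, with 11 of 24 called higher and 1 lower (12 and 1 when adjusted over the list alone; adjusted p = 0.277 with an estimated correlation), Fbln1 at 4.27 ± 0.284 and Col4a5 at 2.19 ± 0.366. The TGF-beta and BMP list rose, with 10 of 21 called higher and 0 lower (15 when adjusted over the list alone; adjusted p = 0.22 with an estimated correlation), and Id2 and Ltbp3 at 2.35 ± 0.557 and 1.75 ± 0.0960. Integrins and adhesion genes had 14 of 29 higher and 3 lower (15 and 3 when adjusted over the list alone; adjusted p = 0.238 with an estimated correlation). Proteases and inhibitors had 15 of 34 higher and 5 lower (15 and 6 when adjusted over the list alone; adjusted p = 0.419 with an estimated correlation), and their call was lost without parental replicate 2 (0.073). The mesenchymal list had 7 of 17 higher and 1 lower (8 and 1 when adjusted over the list alone; adjusted p = 0.0484, 0.489 with an estimated correlation), with Pdgfra, a growth factor receptor, at 1.88 ± 0.205. That call was lost without parental replicate 1 or 2, E2 replicate 2, or A replicate 2 or 3 (up to 0.112), with the top gene's share as a covariate and without both libraries with the highest share of the top gene.

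M against the parental population had Serpinb2, an inhibitor of plasminogen activators (identifier 18788, chromosome 1, 107500892 to 107525600), at 11.2 CPM ± 6.46 where the parental libraries had 0 counts, at least 297-fold higher. Igsf11 rose to 11.7 CPM ± 4.81, Lncenc1 to 33.2 CPM ± 12.2 and Havcr2 to 11.6 CPM ± 4.95. Klk10, a kallikrein protease, rose from 1.01 to 10.7 CPM, and Atp13a4, Calcrl and Nmnat2, an enzyme of NAD synthesis, by 2.83 to 3.35 on the log2 scale. Gab1, an adaptor of receptor tyrosine kinases, fell from 10.3 CPM ± 1.19 to 1.23 CPM ± 0.550, Rasef (identifier 242505, chromosome 4, 73714577 to 73791236) from 10.9 CPM ± 2.38 to 1.5 CPM ± 0.242, and Ndufb9 from 41.9 CPM ± 8.55 to 5.81 CPM ± 1.80.

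In M, integrins and adhesion genes rose, with 9 of 29 called higher and 2 lower (13 and 2 when adjusted over the list alone; adjusted p = 0.263 with an estimated correlation), with Itga7 at 2.02 ± 0.463. Epithelial genes had 10 of 32 higher and 1 lower (11 and 4 when adjusted over the list alone; adjusted p = 0.401 with an estimated correlation), with Krt7 at 1.51 ± 0.242. Cholesterol synthesis had 7 of 23 higher and a median of 0.71 (10 when adjusted over the list alone; adjusted p = 0.592 with an estimated correlation). Extracellular matrix had 8 of 24 higher and 1 lower (8 and 4 when adjusted over the list alone; adjusted p = 0.584 with an estimated correlation), with Fbln2 at 1.42 ± 0.226. Proteases and inhibitors had 7 of 34 higher and 3 lower (9 and 4 when adjusted over the list alone; adjusted p = 0.401 with an estimated correlation). The actomyosin list had 5 of 42 higher and 1 lower (the same when adjusted over the list alone; adjusted p = 0.574 with an estimated correlation), with Cnn2 at 1.32 ± 0.306. Stress genes of the ATF4 list fell, 8 of 28 lower and 2 higher (9 and 3 when adjusted over the list alone; adjusted p = 0.238 with an estimated correlation), with Hspa5 at -1.96 ± 0.0910. Class I antigen presentation fell, 7 of 22 lower and 1 higher (10 and 2 when adjusted over the list alone; adjusted p = 0.269 with an estimated correlation), with Tap2 at -1.49 ± 0.379. Without M replicate 2 the calls of cholesterol synthesis (adjusted p = 0.0806), extracellular matrix (up to 0.143), proteases (up to 0.102) and actomyosin (up to 0.199) were lost. The last 3 of these, and the epithelial list (0.0626), were lost without parental replicate 2. With fry the calls of cholesterol synthesis (0.111), extracellular matrix (0.093) and actomyosin (0.0611) were lost.

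**Figure D4:**
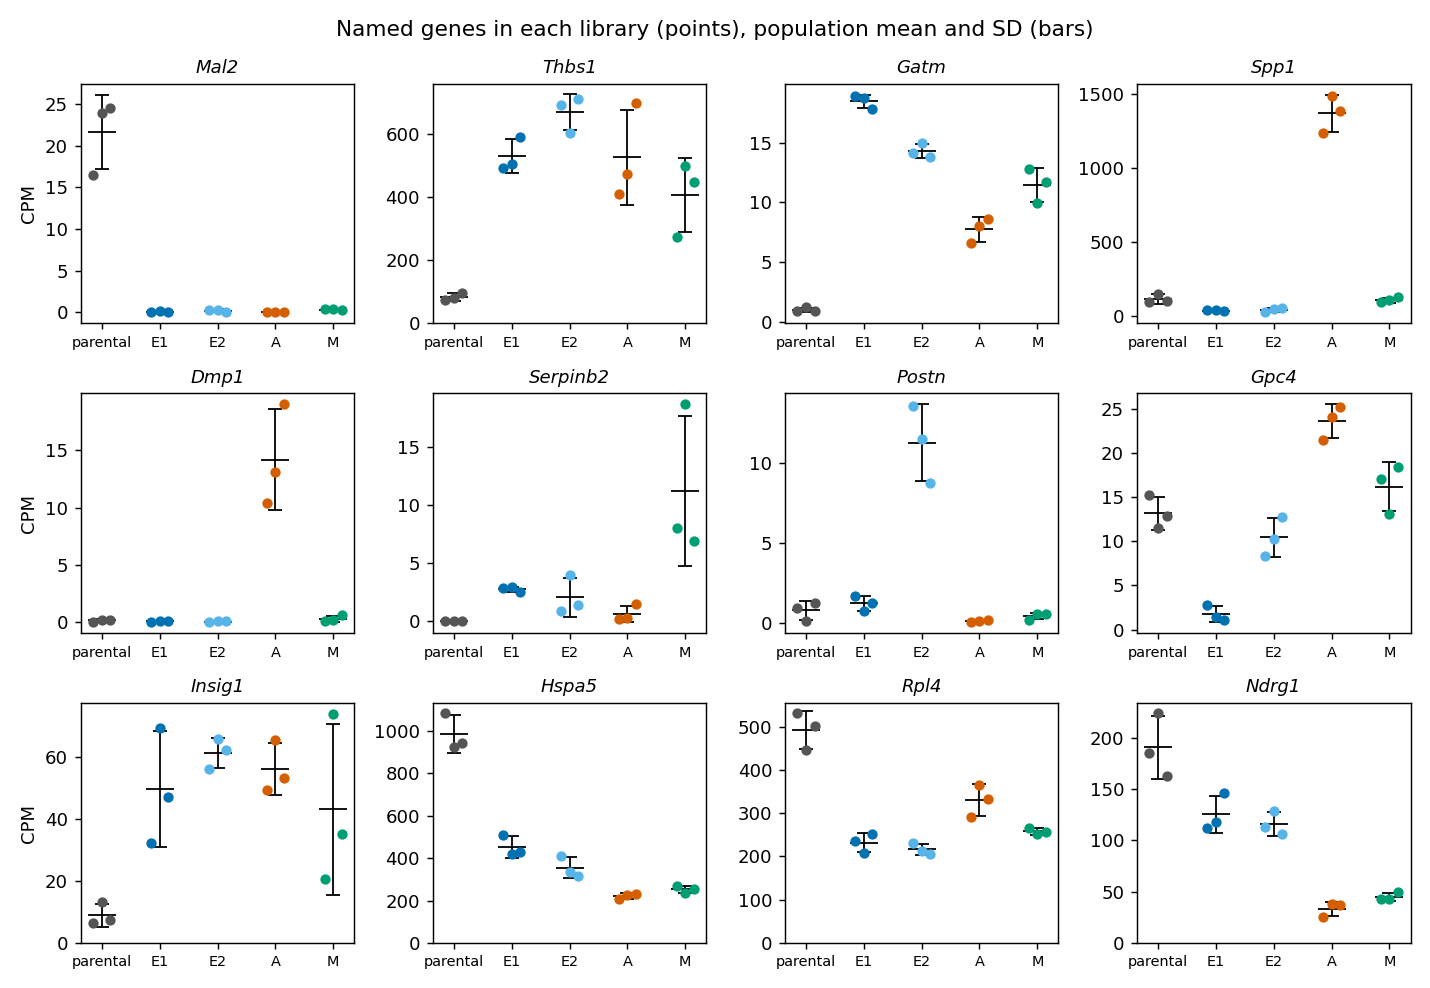
CPM of 12 named genes in each library (points), with the mean and SD of the 3 replicates of each population (bars), on linear axes. Mal2 stood at 21.6 CPM in the parental cells and between 0.0205 and 0.318 CPM in the clones, and Spp1 at 1373 CPM in A.

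Comparisons between clones hold no difference between parental and clonal handling, since all clones were made alike. E2 and E1 were the closest: 30 genes were called, 22 higher and 8 lower in E2. Postn was at 11.3 CPM ± 2.41 in E2 and 1.21 CPM ± 0.461 in E1 (log2 fold change 3.13, SE 0.367, adjusted p = 0.00451). Gpc4, a cell surface proteoglycan (identifier 14735, chromosome X, 52051007 to 52164923), was at 10.4 CPM ± 2.21 in E2 and 1.75 CPM ± 0.910 in E1. Fermt2, an integrin activator, was lower in E2, at 11.1 CPM ± 0.743 against 21.0 CPM ± 1.40, a call lost without E1 replicate 2 (adjusted p = 0.0549). Slc4a4, Rnu3b2, Bcl2l15, Oasl1 and Esd completed the named genes, each lost without at least 4 of the 6 libraries in turn (adjusted p up to 0.262). The count was 9 without E2 replicate 3, 12 to 17 without any 1 of the E1 replicates, 39 without E2 replicate 1, 128 with no filter and 126 with DESeq2. The lists called were extracellular matrix (higher, 1 of 24 genes called, median 0.30) and, lower in E2, glycolysis, the ATF4 list, immediate early genes and ribosomal proteins, each with 0 called members. Adjusted p was 0.484 to 0.560 with an estimated correlation, and none of the 5 was called by fry. The call of glycolysis was lost without E1 replicate 2 or 3 or E2 replicate 2 (up to 0.0951), of the ATF4 list without E1 replicate 2 or E2 replicate 3 (up to 0.138), of immediate early genes without E1 or E2 replicate 1 (up to 0.189) and without both libraries with the highest share of the top gene, and of ribosomal proteins without E2 replicate 3 (0.12).

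A differed from E1 by 3767 genes (1905 higher and 1862 lower in A) and from E2 by 2849 (1455 higher and 1394 lower). Fbln1 had 0 counts in E1 and 6.01 CPM ± 1.75 in A, at least 173-fold higher. Serpinb5 had 0 counts in A, at least 162-fold lower than in E1 and at least 271-fold lower than in E2. Arrdc3 was at 40.8 CPM ± 3.45 in A and 0.539 CPM ± 0.363 in E1, and Serpine2, an inhibitor of serine proteases, at 15.2 CPM ± 0.936 in A and 0.174 CPM ± 0.113 in E1. The milk protein gene Csn3 was at 7.25 CPM ± 0.363 in A and 0.115 CPM ± 0.173 in E2, and the small RNA gene Rny1 at 8.14 CPM in A against 92.1 CPM in E1 and 106 CPM in E2.

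Cholesterol synthesis was lower in A than in E1 (14 of 23 called, 17 when adjusted over the list alone, median -1.36) and E2 (16 of 23, 18 when adjusted over the list alone, median -1.31), and fatty acid synthesis lower than in E2 (8 of 18 lower and 1 higher), each with adjusted p = 0.484 with an estimated correlation. The ATF4 list was lower in A than in E1 (18 of 28 lower and 3 higher, median -0.89) and E2 (18 lower and 5 higher, median -0.74), both with adjusted p = 0.0501 with an estimated correlation, with Mthfd2, a mitochondrial folate enzyme, at 26.4 CPM in A, 107 in E1 and 100 in E2. Class I antigen presentation was higher in A (12 of 22 higher against E1, and 10 higher and 4 lower against E2; adjusted p = 0.357 and 0.484 with an estimated correlation), with H2-D1, a heavy chain gene, at 77.4 CPM in A and 32.1 CPM in E2. Mitochondrially encoded genes were higher in A, 11 of 15 called against E1 and 9 against E2 (0.484 for both with an estimated correlation), with mt-Nd1 at 1157 CPM in A and 690 CPM in E2. The extracellular matrix list, the TGF-beta and BMP list, the mesenchymal list and integrins were higher in A than in either, and glycolysis and replication-dependent histones lower. The calls of their members are not given here, so these results rest on camera alone. With an estimated correlation the adjusted p was 0.212 and 0.203 for TGF-beta and BMP, 0.484 and 0.521 for glycolysis, 0.645 and 0.687 for histones, and 0.484 for the others. Both calls of integrins were lost with the top gene's share as a covariate, and both of histones with fry (0.097 and 0.19). Ribosomal proteins were higher in A than in E2 with 8 of 39 higher and 1 lower, a call lost with an estimated correlation (0.637) and with fry (0.0815). Calls against E2 of glycolysis (0.0821), ribosomal proteins (0.114) and histones (0.0778) were lost without 1 library, in turn E2 replicate 3 or A replicate 1, E2 replicate 3 or A replicate 2, and E2 replicate 2.

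M differed from E1 by 495 genes (309 higher and 186 lower in M) and from E2 by 445 (245 higher and 200 lower). Without M replicate 2 these counts were 824 (395 higher and 429 lower) and 723 (308 higher and 415 lower), so that the majority turned to lower genes, without E1 replicate 2 or 3 or M replicate 3 the first was 210 to 222, and without E2 replicate 1 or M replicate 3 the second was 241 (112 higher and 129 lower) or 208. With only the 6 libraries compared, M against E2 had 71 higher and 103 lower. Gpc4 was at 16.2 CPM ± 2.75 in M against 1.75 CPM in E1, and Calcrl at 6.60 CPM ± 1.87 against 1.12 CPM. Rasef was at 1.5 CPM in M, 14.9 CPM ± 0.789 in E1 and 12.7 CPM ± 2.35 in E2. Slit2, a guidance ligand, and Flnc, a filamin, were higher in M than in E2, by 1.71 ± 0.442 and 1.74 ± 0.239. Slc4a4, a bicarbonate transporter, and Slco5a1 were lower, with log2 fold changes of -2.99 ± 0.138 and -3.04 ± 0.208, as was Postn, at 0.422 CPM ± 0.213 in M.

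Proliferation genes were lower in M than in E1 (3 of 34 called, median -0.59) and E2 (1 of 34, median -0.56), both with adjusted p = 0.484 with an estimated correlation, with Ccna2 at 42.2 CPM in M, 85.0 CPM in E1 and 97.3 CPM in E2. The E1 difference of Ccna2 was lost without E1 replicate 2 or 3 or M replicate 3 (adjusted p up to 0.111) and with only the 6 libraries of the 2 populations (0.166). The hypoxia list was lower than in E1 (2 of 22 called) and E2 (3 lower and 1 higher), with adjusted p = 0.212 and 0.159 with an estimated correlation, with Ndrg1 (identifier 17988, chromosome 15, 66929318 to 66969641) at 44.8 CPM in M, 125 in E1 and 116 in E2, and Ddit4 at 15.1 CPM in M and 34.3 CPM in E2. The E1 call of the list was lost without M replicate 2 (0.0553). Cholesterol synthesis (2 of 23 and 3 of 23 called lower) and histones (1 of 18 and 0 of 18) were lower than in both, with adjusted p = 0.484 to 0.549 with an estimated correlation. These 4 calls were lost with fry (0.0793 to 0.166). The mesenchymal list, the extracellular matrix list, integrins and interferon response were higher than in E1, with 3, 6, 3 and 1 members called higher and adjusted p = 0.484, 0.521, 0.484 and 0.321 with an estimated correlation. Glycolysis (2 lower) and the ATF4 list (2 lower and 1 higher) were lower than in E1, both with adjusted p = 0.484 with an estimated correlation. Against E2, ribosomal proteins (1 higher), proteases (4 higher and 2 lower) and immediate early genes (1 higher) were higher and fatty acid synthesis (0 called) lower, with adjusted p = 0.484 to 0.645 with an estimated correlation. With fry these 4 calls (0.0815 to 0.274) and those of extracellular matrix (0.132) and glycolysis (0.0725) against E1 were lost. Without both libraries with the highest share of the top gene, those of interferon response against E1 and of proteases and immediate early genes against E2 were lost. Without 1 library at a time the calls of extracellular matrix (0.284), integrins (0.22), interferon response (0.102) and the ATF4 list (0.11) against E1 were lost, the first without M replicate 2 alone and the others without M replicate 2 or 1 or more other libraries. Those of proteases (0.335), fatty acid synthesis (0.17), ribosomal proteins (0.188) and immediate early genes (0.166) against E2 were lost too.

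M and A differed by 2256 genes, 1169 higher and 1087 lower in M, and without A replicate 3 the count was 1479. Adam12, a metalloprotease, was at 21.0 CPM ± 8.24 in M and 2.75 CPM ± 0.986 in A, and Klk10 at 10.7 CPM ± 3.93 and 1.83 CPM ± 0.400. Adamts9, another metalloprotease, was at 0.185 CPM ± 0.266 in M and 9.09 CPM ± 2.65 in A, and Galnt15 at 0.279 and 12.7 CPM. The ATF4 list was higher in M (16 of 28 higher and 2 lower; adjusted p = 0.0501 with an estimated correlation), with Ppp1r15a at 45.0 CPM in M and 8.17 CPM in A. Cholesterol synthesis was higher in M (9 of 23; adjusted p = 0.549 with an estimated correlation), a call lost with fry (0.0855). Class I antigen presentation (10 of 22; 0.212), mitochondrially encoded genes (8 of 15; 0.484), extracellular matrix (6 lower and 2 higher of 24; 0.484) and the TGF-beta and BMP list (9 lower and 1 higher of 21; 0.203) were lower in M, where the last value in brackets is the adjusted p with an estimated correlation.

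Genes that set 1 clone apart from all 4 other populations by 2-fold or more were most numerous in A, with 329 (213 higher and 116 lower). Dmp1, Fbln1, Tfpi, Spp1, S100a16 and Galnt15 were the highest by the rule, and Ciart, Atf3, Plk2 and Adam12 the lowest. Spp1 was at 36.6 to 116 CPM in the other populations. Ciart, a circadian regulator, was at 1.69 CPM ± 0.506 in A and 9.01 to 13.7 CPM elsewhere, and Plk2, a kinase, at 17.6 CPM ± 3.53 in A and 77.3 to 161 CPM elsewhere. The call of Galnt15 against the parental population was lost without A replicate 3 or parental replicate 3 (adjusted p up to 0.089) and with the top gene's share as a covariate (0.0643), and that of S100a16 against M with DESeq2, without A replicate 3 or M replicate 1 or 2 (up to 0.0727), and with the top gene's share of counts as a covariate (0.303). M was set apart by 9 genes, 8 of them lower, with Rasef, Syt13 and Sorl1 named by the rule. The call of Sorl1 against E1 was lost without any of 5 libraries in turn (up to 0.199) and from the 6 libraries of M and E1 alone (0.0885), and against E2 without E2 replicate 1 (0.0619) and without both libraries with the highest share of the top gene (0.058), and that of Syt13 without E1 replicate 3 (0.105). The 1 higher gene was Ngfr, a neurotrophin receptor, named after its values were seen. E1 was set apart by 8 genes, all lower, with Gpc4 and Trib2 named by the rule, and E2 by 2, Postn and Rnu3b2, both higher. Without M replicate 2 the M count was 38 and without M replicate 3 it was 2, and it was 5 or 3 without E1 replicate 1 or 3. The E1 count was 3 to 5 without E1 replicate 2 or 3 or E2 replicate 3, and the E2 count was 1 without E1 replicate 2 or 3 or E2 replicate 2 or 3.

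Of the lists fixed in advance, 11 were not called in any of the 10 comparisons. The lowest adjusted p was 0.0506 for NRF2 targets and for heat shock, 0.0523 for YAP targets, 0.0536 for cytokines and chemokines, 0.0816 for drug efflux and metabolism, 0.093 for stem and tumour-initiating genes, 0.108 for Wnt response, 0.114 for basal mammary, 0.162 for p53 targets, 0.189 for growth factor receptors and ligands, and 0.23 for luminal mammary genes. Markers of other cell types were too few to test: 2 of 16 leukocyte, 3 of 15 fibroblast and 2 of 14 endothelial markers passed the filter. The leukocyte markers Cd74 and Cd68 were at 0.381 to 4.34 CPM and 0.379 to 0.690 CPM across populations. Among fibroblast markers, Fbln1, also a member of the extracellular matrix list, was at 6.01 CPM in A, C3 at 2.86 to 9.70 CPM and Gsn at 35.2 to 86.8 CPM. The endothelial markers Eng and Egfl7 were at 7.20 to 19.5 CPM and 0.586 to 0.936 CPM.

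The deposited result table of the authors held 2530 genes at an adjusted p under 0.05 of 12922 with an adjusted p, 1282 higher and 1248 lower. Across 12712 genes, its log2 fold changes correlated best with those of M against A (-0.936, so with the opposite sign), and the next comparison reached 0.772 in absolute value. Of the genes called in it, 2233 were called between M and A here in the same direction once the sign was turned.

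**Figure D5:**
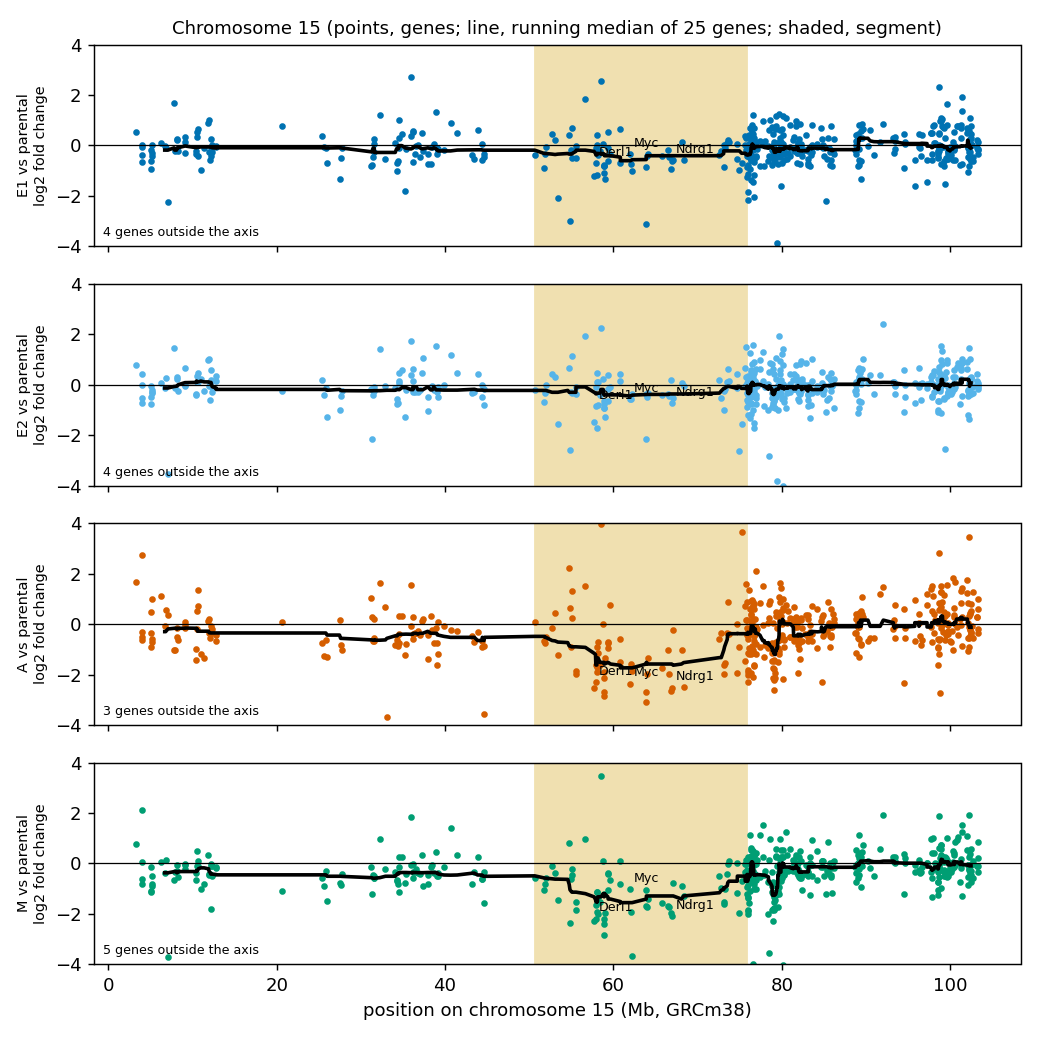
Log2 fold change of chromosome 15 genes against the parental population (vertical axis) by position in Mb on GRCm38 (horizontal axis), 1 panel per clone, with a running median of 25 genes as a line and the segment from 50.7 to 75.9 Mb shaded. The median of the segment's 75 genes was -0.92 in A and -1.04 in M.

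Where on the genome the changes lay was examined after the data were seen. On chromosome 15, from 50.7 to 75.9 Mb, the 75 tested genes had a median log2 fold change of -0.92 in A and -1.04 in M, and -0.36 in E1 and -0.30 in E2, against the parental population. These bounds hold the windows of A with a median beyond 0.5 of that of its lowest window. The runs of windows past the percentile of shuffles were wider, from 36.6 to 75.9 Mb (100 genes, median -0.72) and again from 76.5 to 80.1 Mb (75 genes, median -0.47, 28 called lower and 6 higher) in A, and from 3.3 to 80.1 Mb in M (275 genes, median -0.50), and E1 passed it from 50.7 to 75.9 Mb. In A 42 of the 75 genes were called lower and 6 higher, and in M 40 lower and 2 higher. Myc, named after its values were seen, changed by -2.36 in A and -1.03 in M, and Ndrg1 by -2.52 and -2.09. Mal2, Ndufb9 and Ndrg1 lie in this segment too. On chromosome 14, from 7.8 to 121.3 Mb, the 400 tested genes had a median of -0.74 in E2, 351 of them below 0 and 182 called lower. Over all 413 tested genes of that chromosome the median was -0.46 in E1, -0.75 in E2, -0.30 in A and -0.34 in M. Chromosome 8 was lower in all 4 clones too, with a median over its 674 tested genes of -0.34 in E1, -0.25 in E2, -0.30 in A and -0.38 in M, the last the lowest of any chromosome in M, and runs of windows past the percentile in each clone. On chromosome 9 the median was -0.34 in E1 and 0.25 in A.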

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

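The tests of the top gene's share of counts, of length and expression in single clones and of a common origin of E1 and E2 were chosen only after the results they concern had been seen, and the patterns on chromosome 15, in ribosomal protein genes and between E1 and E2 were themselves noticed in these data.

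The changes of the clones from the same 3 parental libraries were compared between clones. In such a difference the parental term cancels, so its test is the comparison between clones given above, not a further one. By that test the changes differed between clones. This held for 30 genes between E2 and E1, 3767 between A and E1, 495 between M and E1, 2849 between A and E2, 445 between M and E2 and 2256 between M and A. Among them, genes called in opposite directions from the parental level numbered 1, 152, 4, 72, 4 and 40. Serpinb5 was higher than parental in E1 (log2 fold change 3.16, adjusted p = 4.67e-05) and lower in A (0 counts against 0.519 CPM in the parental population, adjusted p = 5.89e-05). Arrdc3 was lower in E1 (-3.51) and higher in A (2.48), Spp1 lower in E2 (-1.45) and higher in A (3.57), and Trib2 lower in E1 (-1.22) and higher in M (1.07). Slco5a1 and Ddit4, also opposite between M and E2, were named by the rule. The rest of the small counts, named after their values were seen, were Chst2 between E2 and E1, Atad2, Snn and Abhd2 between M and E1, and Atad2 and Abhd2 between M and E2.

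The first pattern is the segment of chromosome 15, where A and M were lower. Genes elsewhere matched on GC content, length and expression had 0.009 of the segment's median change in A, which argues against those properties, and all 6 libraries of A and M showed the shift, with medians from -0.89 to -1.16, which argues against a single library. Fewer copies of the segment in A and M may account for it, and the prediction was a median below -0.5 in M against E1 in both the lower and the higher expressed part of the genes. It was -0.302 in the lower and -0.914 in the higher expressed part, so the test did not decide, and DNA was not measured. E1, the reference of that test, was itself at -0.359 against the parental population. The genes within the bounds were also uneven, with quartiles of -1.145 and -0.151 in M against E1.

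The second pattern is the lower level of ribosomal protein genes in all 4 clones. With the top gene's share as a covariate the list's medians were -0.579 in E1, -0.731 in E2, -0.354 in A and -0.555 in M. Its adjusted p by camera at the preset correlation was at most 0.000959, which argues against that share. With an estimated correlation the list was not called even without the covariate. Members without a pseudogene of their name had medians from -0.72 to -0.342. Pseudogenes under other names were not counted, so this cannot decide whether reads shared with pseudogenes matter. Genes matched on length and expression had 0.252 of the list's change on average over the 4 clones, just above the bound of 0.25. They had at most 0.187 of it in E1, E2 and M, which argues against length and expression as the whole cause there, and 0.519 in A, where these may account for part of it. Handling as a clone, growth rate and RNA quality were not tested.

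The third pattern is the small number of genes between E2 and E1. The replicate spread of E1 and E2 was 1.024 times that of A and M, which argues against a larger spread. A common origin of E1 and E2 within the parental line may account for it and was tried with 2 tests. The first counted genes near silent in both E1 and E2 and expressed in the other 3 populations and found 0, as in every other pair of clones, so it decided nothing. The second was chosen after that outcome and counted genes called at 2-fold or more in 1 direction in both against each of the other 3 populations: 18 for E1 and E2, below the 33 of A and M, of which 15 lie in the chromosome 15 segment. The genes of that segment can stem from 1 event, which the bound set for this test did not allow for, and outside it the counts were 18 and 18. That tie rests on the bounds of the segment, since A and M were also lower next to it, and outside the whole of chromosome 15 the counts were 17 and 12. A count 2 times that of any other pair was set as the bound for a common origin, which no version reached. The bound set against it was that E1 and E2 do not have the largest count of all pairs, and the 33 of A and M met it. As written, the second test thus came out against a common origin. That outcome rests on the chromosome 15 genes, and leaving them out was a condition added after it was seen. For this reason a common origin stays open.

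For each pair of populations, 3 against 3 libraries make 10 splits, too few for a share under 0.05, and the real split counted as 1 of them with as many genes in each of the 10 comparisons. The real counts and the highest of the other splits were 1922 and 0 for E1, 2281 and 0 for E2, 3814 and 0 for A and 1798 and 0 for M against the parental population. They were 30 and 1 for E2 against E1, 3767 and 0 for A against E1, 495 and 54 for M against E1, 2849 and 0 for A against E2, 445 and 13 for M against E2, and 2256 and 0 for M against A.

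Splits of all 15 libraries were drawn 40 times with the real one included. Only the real split, 1 of 40, was as large for the 5200 genes with any difference (highest other 4), for the 532 genes shared by the 4 clones (0), and for the genes that set apart the parental population (154 and 0), E1 (8 and 0), E2 (2 and 1), A (329 and 0) and M (9 and 0). The other splits mix populations, which by construction adds their differences to the spread within groups and holds these counts low. With 1 of 40 splits as large, they argue against a random grouping of the libraries for the genes with any difference. They measure no more than that, and are no evidence for single small counts. For E2 the real 2 fell to 1, the highest other, without E1 replicate 2 or 3 or E2 replicate 2 or 3, so chance is not excluded there. For gene lists the real 43 calls against the parental population stood near the highest other, 36, with a median of 24. Between clones 7 of 40 splits reached the real 51, with 70 as the highest and 37 as the median. Unevenly mixed groups can carry differences between populations into the list tests. For lists these splits are therefore no baseline of chance alone. They do not exclude chance there, and the number of lists called is weak evidence in both.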

How the results depend on the processing

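The covariate for the top gene's share, the fit without the 2 libraries with the highest share, the fit without the 6 genes with the most counts and the likelihood ratio test were chosen after seeing the data. No named gene reversed, but the majority of higher over lower genes turned under at least 1 alternative in 8 of the 10 comparisons, all except M against the parental population and E2 against E1. With no filter E2 against E1 had 128 genes, M against E1 817 and M against E2 790, and E1 and E2 were set apart by 27 and 7 genes. DESeq2 gave 126 for E2 against E1, 743 for M against E2, and 28 and 6 genes setting E1 and E2 apart. Only the 6 libraries compared gave 174 for M against E2. The covariate gave 63, 781 and 757 for E2 against E1, M against E1 and M against E2, and the fit without 2 libraries 1440 for E2 against parental and 64 for E2 against E1. With an estimated correlation 1 and 0 gene lists were called. Causes were not tested. Of 464 named calls, 375 were kept under every alternative and 89 lost under at least 1. The likelihood ratio test gave 5814 genes with any difference; the Wald test planned for it takes 1 contrast and was not run.

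Replicate numbers were checked as pairs: 4 of 30 same-number pairs correlated above 0.1 (range -0.058 to 0.213), where all 30 were required, so the libraries were not treated as paired. The best partner had the same number in 25 of 30 cases, where chance gives 10, a hint of pairing from the data that the labels do not give. Replicate 1 also had the highest share of the top gene in each population. That share was 49.3% in the parental library, 44.1% in E1, 49.1% in E2, 39.3% in A and 44.7% in M. The main fit had no term for the replicate number, so it does not allow for such a pairing. With the replicate block every one of the 10 comparisons had more genes, from 1.09 to 2.27 times, with 68 for E2 against E1 and 699 for M against E2.

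Leaving out 1 library at a time gave 1084 to 1630 genes for E1, 1569 to 2011 for E2, 2997 to 3538 for A and 1145 to 1751 for M against the parental population. It gave 9 to 39 for E2 against E1, 2938 to 3135 for A against E1, 210 to 824 for M against E1, 2019 to 2368 for A against E2, 208 to 723 for M against E2 and 1479 to 2003 for M against A. Any difference ranged from 4362 to 5476, and genes setting apart from 117 to 157 for parental, 3 to 10 for E1, 1 to 3 for E2, 245 to 331 for A and 2 to 38 for M. Genes shared by the 4 clones ranged from 354 without parental replicate 3 to 548, and lists from 28 without parental replicate 2 to 46 against parental and 49 to 60 between clones. The smallest library had 6164768 counts outside the top genes, and of simulated 2-fold changes 59% were called, so a gene without a call is not shown to be unchanged. Detection by expression level was not measured.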

Other observations

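Some biology lies outside the comparisons above. Beyond E1 and E2, the pairs E1 and M, E2 and M, A and M, E2 and A, and E1 and A shared 924, 1063, 1162, 1236 and 823 genes called in the same direction from the parental level. The correlation of log2 fold changes across genes was 0.789 for E1 and E2, 0.708 for E2 and M, 0.697 for E1 and M, 0.582 for A and M, 0.512 for E2 and A and 0.358 for E1 and A. Simulated libraries without differences, which share the parental libraries, gave 0.50 to 0.507. Shared libraries add to a correlation less where changes are large, so these values do not rank the pairs by what they share. The covariance was in the same order 0.484, 0.415, 0.406, 0.395, 0.366 and 0.255, against 0.089 to 0.09 in the simulation. Genes called at 2-fold or more in both E1 and E2 against each other population, named after their values were seen, were Gdnf, Il18rap, Nrp1, Tnfrsf26 and AU018091 (higher), and 13 lower ones with Hexa, Rbpms, Serpine2 and Spp1 among them.

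Cdkn2a and Cdkn2b, neighbouring cell cycle inhibitor genes on chromosome 4, had 0 counts in all 15 libraries, which allows up to 0.00691 CPM over them together, while Mtap, also nearby, had a mean of 8052.5 counts per library. In windows of 50 genes along the chromosomes, 38 of 465 lay beyond the threshold in E1, 25 in E2, 10 in A and 43 in M against the parental population. The threshold was the 95th percentile, over shuffles, of the largest absolute median among all windows of a shuffle. Few shuffles therefore held even 1 window past it. On chromosome 13 from 21.4 to 31 Mb, which holds replication-dependent histone genes, the median was 0.71 in E1 and 0.68 in E2. Few of its 75 tested genes were called: 7 higher and 2 lower in E1, and 5 higher and 2 lower in E2.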
